A study of Saccharomyces cerevisiae with 13 samples.

How the data were processed

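The samples were the 13 time points of a time course of budding yeast (Saccharomyces cerevisiae), taken every 10 min from 0 to 120 min after release from an arrest with alpha factor, the mating pheromone that halts MATa cells in G1. Per the labels, RNA of each time point was labelled with Cy5 and hybridised on a 2-colour array against Cy3-labelled RNA of an asynchronous culture. Each time point has 1 array and there were no replicates, so the precision is limited by the number of arrays, 13. The sample titles carry 2 different file stamps, 1 shared by the 4 arrays from 0 to 30 min (set A) and 1 by the 9 arrays from 40 to 120 min (set B). The set follows time. The stamps have the form of dates, and set A, with the earlier time points, carries the later date. What the stamps record is not stated, so whether both sets come from a single run of the time course is not known.

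The deposited values are log10 ratios, 1 per feature and array. The base is stated nowhere and was read from the values: they end exactly at 2 and -2, which is 100-fold in base 10, and their quartiles lie near 0.05 on both sides of 0. The scanner, the background correction, the normalization, the flagging and the averaging of spots are not given in the sources used here. Array medians lay close to 0, from -0.0031 to 0.00736 on the log10 scale. The direction of the ratio is also unstated. It was taken as time point over reference, called likely because the median log2 ratio of 26 genes induced by pheromone was 1.88 at 0 min. With the opposite direction all peaks would become troughs.

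Values were turned into log2 by multiplying by 3.32. Of 80493 values, 272 lay at or beyond 1.99 on the log10 scale in size (184 of them at the upper limit, 205 in set A and 67 in set B). Such a value is a bound, and it was treated as missing. This was decided before any test was run, and keeping these values is an alternative added after seeing the files. Genes with values on at least 11 of the 13 arrays were tested. The files hold 6205 rows with open reading frame IDs, of which 5703 were named through the RefSeq gene table of assembly R64 and 502 were not and keep their ID. A further 12 rows are control rows and stayed out of the tests. No coordinates are printed because the files name no build.

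Periodic genes were found with limma 3.58.1 in R 4.3.3. Each gene was fitted with the array set and a cosine and sine of a 60 min period, since the design text places 2 cycles in the 120 min. The moderated F test of the cosine and sine, with 9 residual degrees of freedom for a gene with values on all 13 arrays and fewer otherwise, was adjusted by Benjamini-Hochberg over 6183 genes, with a threshold of 0.05. The error is the residual around the curve, because no time point was repeated, and it holds curve misfit as well as measurement error. Peak-to-trough size is the full height of the fitted curve, with its SE, and the peak time is given in min within the 60 min cycle. For each of 19 gene lists the mean profile of the gene-centred values was tested by a permutation test, with 100000 shuffles of the arrays within each set, two-sided by construction, and Benjamini-Hochberg adjustment over the 19 lists. The smallest p it can give is 1e-05. The deviation at 0 min is the limma coefficient of an indicator for that array added to the periodic model. A list's median deviation was set against 10000 random lists of its size. Its error assumes that the 0 min array varies like the others. Differences between 0 min and later arrays, correlations between arrays and ranges of profiles have no test. The best period was read from a grid of 40 to 90 min in steps of 1 min over the genes of 7 lists. Lists were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots with matplotlib 3.10.9.

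The gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined, except for those the closing section names as chosen after seeing the data. The 7 phase lists hold genes known for G1/S replication and repair, G1/S budding and cell wall, core histones, spindle and kinetochore, the G2/M CLB2 cluster, M/G1 genes with an early cell cycle box (ECB), and the M/G1 SIC1 cluster. The other 12 cover pheromone response, MATa-specific, MATalpha-specific, meiosis, methionine, phosphate, cytosolic ribosomal proteins, ribosome biogenesis, proteasome, glycolysis, stress response and oxidative phosphorylation. These lists were written from general knowledge of yeast, and several phase lists stem from earlier time courses of this kind. The rule for periodic genes names 16 cell cycle regulators whatever their result (1 of them is not reported here), up to 3 called members of each list with the largest fitted size, and the 5 largest called genes in no list. For 0 min it names the 8 largest called deviations on each side and 10 pheromone genes whatever their result. Genes named outside the rule are marked as such.

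The fits were tested on simulated data. Among 6183 simulated genes the periodic test recovered 32% of planted rhythms of 0.5 log2 peak to trough, 82% of 1 and 100% of 2, with 3.09% false calls. Among 6153 simulated genes, the 0 min test recovered 70% of deviations of -1 and 54% of 1, with 3.13% false calls. A test for different curves in both cycles recovered 82.5% of planted differences of 2 log2 over 6183 genes, with 3.51% false calls. The list test gave p below 0.05 in 6.5% of 400 profiles without a rhythm. It did so in 99% of 400 with a rhythm of 1 log2 peak to trough and a noise SD of 0.2. Smaller rhythms of a list were not simulated. Alternatives covered the scaling of the arrays, the missing-value filter, the array set, the period, the shape of the curve, the shrinkage, the threshold, and leaving out each array in turn.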

Results

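Transcript levels of budding yeast were followed through 2 nominal cell cycles after release from alpha factor, in 13 samples taken every 10 min. Each sample was compared with an asynchronous culture on its own 2-colour array. Between 6157 and 6204 of 6205 open reading frames had a value on each array. The spread of the log2 ratios was widest at 10 min (SD 0.63) and narrowest at 110 min (SD 0.31). Because each time point has 1 array, errors are standard errors from the residuals around a fitted curve and the direction of each ratio is the likely one, time point over reference.

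The first question was which transcripts oscillate with the cell cycle. At a 60 min period, 338 of 6183 genes (5.47%) were periodic by limma at an adjusted p under 0.05. Their median peak-to-trough size was 0.97 log2 (quartiles 0.66 and 1.40), and 156 of them spanned at least 1 log2, a 2-fold range. The phase lists supplied 77 of the calls from 161 measured genes. Among the calls, 12 are IDs that the gene table does not hold. Most peaks lay between 10 and 40 min, with 88 genes between 10 and 20 min, 91 between 20 and 30 min and 70 between 30 and 40 min, against 31 between 0 and 10 min, 34 between 40 and 50 min and 24 between 50 and 60 min. The outermost 5 genes at each chromosome end supplied 22 calls that peak between 13 and 17 min, and 7 of the called genes are copies of the subtelomeric gene family YRF1, which are not separate measurements if their spots share signal. At an unadjusted p under 0.05 there were 1309 genes.

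The count depends on the setting: it was 548 with quantile-normalized arrays, 73 with a second harmonic, 107 with an ordinary F test, 143 without the 70 min array, 6 at a 55 min period and 0 at 50 min (limma, with 449 at an unadjusted p under 0.05), but 357 at 65 min. Of 39 called genes named here, 19 stayed called whichever array was left out, among them RNR1, RFA1, HSL1, HCM1, SVS1, the histones, the MCM genes, SIC1 and ASH1. The others lost their call at least once in 13 such fits, CLN3 in 12, PCL1, MFA1 and PHO5 in 10, STE2 in 9, TOS6 and HAS1 in 8, CLN1 in 7, PGM2 in 6, CLN2 in 5, MCD1 and MSA2 in 4, CDC20, GPA1, STU2 and SPC97 in 3, EGT2 and SCW10 in 2, and ALK1 and STE6 in 1.

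**Figure D1:**
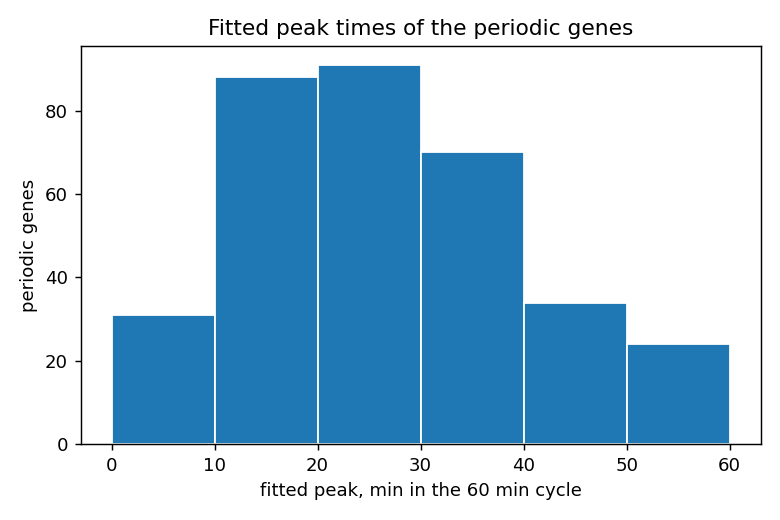
Number of periodic genes (y axis) by fitted peak time in 10 min bins of the 60 min cycle (x axis). The bin from 20 to 30 min holds 91 genes and the bin from 50 to 60 min holds 24.

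Genes of the G1/S transition formed the first large group. Of 33 measured genes for DNA replication and repair, 21 were periodic (29 adjusted over the list alone), with a mean peak at 19.8 ± 1.6 min (circular SD, n = 21). RNR1, the large subunit of ribonucleotide reductase, spanned 7.78-fold (2.96 ± 0.40 log2, SE, adjusted p = 0.00411). MCD1, a cohesin subunit, spanned 2.47 ± 0.47 log2 (adjusted p = 0.0239), and RFA1, of the single-strand binding complex, 2.04 ± 0.25 log2 (adjusted p = 0.00383). Of 25 budding and cell wall genes, 16 were periodic (21 adjusted over the list alone), with a more scattered peak at 23.2 ± 6.1 min (n = 16). SVS1 spanned 2.97 ± 0.46 log2, the G1 cyclin PCL1 2.29 ± 0.48 and the kinase HSL1 2.18 ± 0.23. With values at the limit kept, SVS1 and PCL1 did not pass (adjusted p = 0.109 and 0.0576). The mean profiles of both lists were periodic, with adjusted permutation p = 0.00541 and 0.00532 and sizes of 1.28 and 0.95 log2.

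The G1 cyclins peaked in the same part of the cycle. CLN1 and CLN2, which drive cells past Start, spanned 5.04-fold and 5.11-fold and peaked at 21.5 and 21.8 min (adjusted p = 0.0307 and 0.0208). HCM1, a forkhead transcription factor of S phase, peaked at 21.0 min with 1.28 ± 0.17 log2 (adjusted p = 0.00391). CLN3, the cyclin upstream of CLN1 and CLN2, peaked earlier, at 1.3 min, with 1.03 ± 0.23 log2 (adjusted p = 0.0435). SWI4, a subunit of the SBF transcription factor, had a fitted size of 1.33 ± 0.32 log2 (adjusted p = 0.0606), the repressor YOX1 1.98 ± 0.52 (adjusted p = 0.0893) and the S phase cyclin CLB6 2.12 ± 0.65 (adjusted p = 0.153). These 3 genes did not pass, although CLB6 stood at 2.83 log2 at 10 min and 1.04 at 70 min, and all 3 passed with quantile-normalized arrays (adjusted p = 0.00112, 0.0075 and 0.0299). CLB5, the other S phase cyclin, had a size of 0.21 ± 0.10 log2 (adjusted p = 0.395). The largest periodic genes outside the lists were TOS6 at 25.6 min with 2.89 ± 0.61 log2, the open reading frame YBR089W at 18.6 min with 2.52 ± 0.42, and MSA2 at 14.9 min with 2.40 ± 0.46, besides CLN1 and CLN2. YBR089W carries the next number after YBR088C, which is POL30 of the replication list, on the other strand. Whether their spots share signal was not checked, so YBR089W may not be a separate finding. The CLN1 call was lost without the array set in the fit (adjusted p = 0.0634) and at a 65 min period (0.0521), and those of CLN1, CLN3 and TOS6 with values at the limit kept (adjusted p = 0.0529, 0.0678 and 0.0613). TOS6 also missed the threshold with robust shrinkage (adjusted p = 0.0508). CLN3 did not pass within set B alone (adjusted p = 0.105).

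Histone genes followed with the largest swing of any list. Of 9 measured genes, 8 were periodic (9 adjusted over the list alone), all within 29.99 to 31.8 min. The mean profile spanned 2.75 log2 (adjusted permutation p = 0.0019). HTA2, HHF1 and HTA1 spanned 9.50-fold, 8.86-fold and 8.64-fold. The paired histone genes are close copies, so their spots may not be fully separate measurements, which was not tested. Of 38 spindle and kinetochore genes, 9 were periodic (16 adjusted over the list alone), spread around 36.1 ± 8.9 min (n = 9). STU2, a microtubule-binding protein, spanned 1.30 ± 0.25 log2, the separase ESP1 1.04 ± 0.13 and the spindle pole component SPC97 1.03 ± 0.20. STU2 did not pass within set B alone (adjusted p = 0.0752). The mean profile of the list was small, 0.31 log2 (adjusted permutation p = 0.0127), and it did not pass without the 30 min array (adjusted permutation p = 0.0562) or at 55 min (0.104).

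Mitotic genes came late in the cycle. Of 23 genes of the G2/M CLB2 cluster, 8 were periodic (19 adjusted over the list alone), with a mean peak at 52.9 ± 7.0 min (n = 8). CDC20, the activator of the anaphase-promoting complex, peaked at 58.2 min with 1.71 ± 0.33 log2 (adjusted p = 0.0239, and 0.0665 within set B alone). DBF2, a kinase of mitotic exit, peaked at 0.4 min with 1.46 ± 0.23 log2, and ALK1 at 44.7 min with 1.28 ± 0.22. The cyclins CLB1 and CLB2 and the polo kinase CDC5 had fitted sizes of 1.59 ± 0.37, 1.37 ± 0.36 and 1.54 ± 0.41 log2 and did not pass at 60 min (adjusted p = 0.0603, 0.0946 and 0.0981). At a 65 min period all 3 passed (adjusted p = 0.00458, 0.0133 and 0.0137), as they did with quantile-normalized arrays (0.0222, 0.019 and 0.0327) and within set B alone (0.0398, 0.00475 and 0.015). SWI5 (0.86 ± 0.35 log2) and NDD1 (0.67 ± 0.15), transcription factors of mitosis, did not pass (adjusted p = 0.319 and 0.0501). SWI5 passed within set B alone (adjusted p = 0.0427), and NDD1 with quantile-normalized arrays (0.0435), all 13 arrays required (0.049), linear time in place of the set (0.0455), robust shrinkage (0.0496), and without the 100 min (0.0324) or 120 min array (0.0308). The mean profile of the cluster spanned 0.89 log2 (adjusted permutation p = 0.036). That call was lost without the array set (adjusted permutation p = 0.0617), with linear time in its place (0.054) or beside it (0.0508), at 55 min (0.264), and without any 1 of the arrays at 20, 40, 50, 60, 70, 80, 90 or 120 min (0.051 to 0.122).

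The M/G1 groups bridged the 2 cycles. Of 10 genes with ECB elements or a role in loading replication origins, 6 were periodic (9 adjusted over the list alone), with a mean peak at 5.4 ± 1.9 min (n = 6) and a mean profile of 0.91 log2 (adjusted permutation p = 0.00541). MCM5, MCM3 and MCM4, subunits of the replicative helicase, spanned 1.98 ± 0.20, 1.55 ± 0.17 and 1.25 ± 0.18 log2. Of 23 genes of the SIC1 cluster, 9 were periodic (11 adjusted over the list alone), with a mean peak at 11.5 ± 1.9 min (n = 9). EGT2, HSP150 and ASH1 spanned 3.58 ± 0.65, 3.14 ± 0.38 and 2.75 ± 0.36 log2, and SIC1 itself, the inhibitor of B-type cyclin kinase, 3.20-fold (1.68 ± 0.25 log2, adjusted p = 0.00665). The SIC1, EGT2 and ASH1 calls were lost without the array set (adjusted p = 0.339, 0.628 and 0.105), and that of EGT2 also with linear time in its place (0.101). The list had its peak in the second cycle and none at 10 or 20 min: its median log2 ratio was -1.41 at 10 min and -1.73 at 20 min, but 0.54 at 70 min and 0.39 at 80 min. Its mean profile did not pass (1.28 log2, adjusted permutation p = 0.0545), although it did within set B alone (0.00741), without the 0 min (0.00928) or 10 min array (0.0307), with quantile-normalized arrays (0.0111), as a median profile (0.0409) and at 65 min (0.0275).

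**Figure D2:**
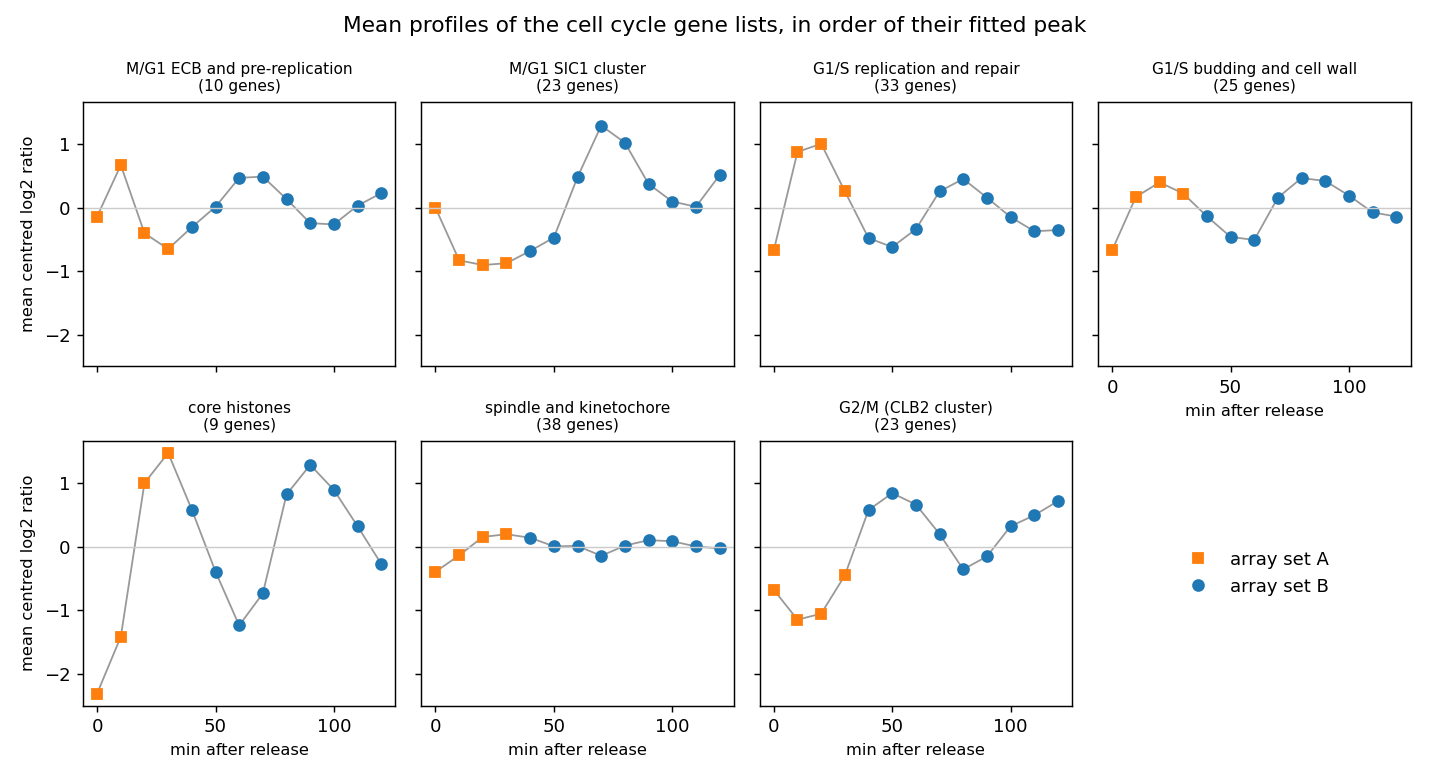
Mean gene-centred log2 ratio (y axis) of each of the 7 phase lists against min after release (x axis), with squares for the 4 arrays of set A and circles for the 9 arrays of set B. Histones rise to 1.47 at 30 min and again to 1.28 at 90 min, while the SIC1 cluster has no peak near 10 min and its highest point at 70 min.

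Among the other lists, the MATa-specific genes were periodic as a group, with 3 of 7 called (6 adjusted over the list alone) and a mean profile of 1.90 log2 peaking at 2.5 min (adjusted permutation p = 0.0117). The profile stood at 2.66 log2 at 0 min and 1.05 at 10 min, but ran only from -0.60 to 0.41 over 60 to 110 min. Its fitted size therefore holds the high start as well as the later, smaller swing. STE2, the alpha factor receptor, spanned 2.26 ± 0.48 log2, the pheromone gene MFA1 2.11 ± 0.46 and the exporter STE6 2.08 ± 0.36. The MFA1 ratio was 2.88 and 2.76 log2 at 0 and 10 min, and between -1.03 and -0.09 over 60 to 110 min. The calls of STE2 and MFA1 were lost with values at the limit kept (adjusted p = 0.0623 and 0.067), with robust shrinkage (0.0518 and 0.0552) and with linear time beside the array set (0.0512 and 0.0525), that of MFA1 also without the array set (0.143) or with linear time in its place (0.0775), and the profile's without the 30 min array (adjusted permutation p = 0.0562) or at 55 min (0.104). The pheromone response list was not periodic as a whole (adjusted permutation p = 0.165), and 2 of 26 members were called (also 2 adjusted over the list alone), GPA1 and SCW10 (2.10 ± 0.39 and 1.21 ± 0.22 log2). SCW10 did not pass without the array set (adjusted p = 0.0625). Within set B alone its profile passed (adjusted permutation p = 0.0393). The ribosome biogenesis profile passed with 0.42 log2 (adjusted permutation p = 0.0361), with 1 of 40 genes called (also 1 adjusted over the list alone; HAS1, 0.60 ± 0.12 log2, which did not pass at 65 min, adjusted p = 0.0757, or within set B alone, 0.0671), and the profile's call was lost at 65 min (0.108), at 55 min (0.0586), with linear time in place of the array set (0.054) or beside it (0.0508), and without any 1 of the arrays at 20, 40, 50, 60, 70, 80, 90, 100 or 120 min (0.0513 to 0.114). Few genes were called in the phosphate list (PHO5 and PHO8, 2 of 18), glycolysis (HXK2, 1 of 19) and stress response (PGM2, 1 of 26), or 4, 3 and 4 adjusted over the list alone. PHO5 and PGM2 did not pass with values at the limit kept (adjusted p = 0.0678 and 0.0511), nor PHO5 with linear time beside the array set (0.0529) and PGM2 within set B alone (0.0677). These lists did not pass (adjusted permutation p = 0.372, 0.0901 and 0.119), although glycolysis did with quantile-normalized arrays (0.042) and stress response with values at the limit kept (0.0162). No gene was called by limma among 137 cytosolic ribosomal proteins, 33 genes of oxidative phosphorylation, 31 proteasome, 23 methionine, 18 meiosis or 4 MATalpha genes, in each case also 0 adjusted over the list alone, while 2, 6, 1, 2, 2 and 0 had an unadjusted p under 0.05. Their profiles had adjusted permutation p = 0.0545, 0.135, 0.748, 0.735, 0.89 and 0.928. With sizes up to 0.245 log2, they lie below the rhythms on which the list test was simulated, so small rhythms could be missed. The ribosomal protein profile, at 0.09 log2, passed with arrays centred on their medians (adjusted permutation p = 0.0404) and without the 60 min array (0.00323).

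The second question was what marks the arrested cells at 0 min beyond their place in the cycle. Against the fitted curve, 194 genes were higher and 128 lower at 0 min among 6153 tested (limma, adjusted p under 0.05). The total of 322 became 89 with quantile-normalized arrays, 214 without the 90 min array and 556 at a 65 min period. The direction of the ratios was itself taken from the pheromone response list at 0 min, so its sign there is assumed and only its size and its common direction are measured. In that list 20 of 26 genes were higher (25 adjusted over the list alone), none was lower, and the median deviation was 2.11 log2, beyond all 10000 random lists of its size (95% of them from -0.15 to 0.15). FUS1, needed for cell fusion, stood 15.2-fold above the curve (3.92 ± 0.44 log2, adjusted p = 0.000455). AGA1, the anchor of the a-agglutinin, deviated by 3.60 ± 0.74 log2, the fusion protein PRM1 by 3.49 ± 0.39, the transcription factor KAR4 by 3.39 ± 0.25, the GTPase activator SST2 by 3.26 ± 0.34 and the kinase FUS3 by 2.58 ± 0.24. FAR1, the inhibitor that holds cells in G1, deviated by 3.62 ± 0.53 log2 and FIG1 by 2.47 ± 0.49. Of the MATa-specific genes 5 of 7 were higher (6 adjusted over the list alone), with a median of 2.49 log2. Among them were BAR1, the protease that degrades alpha factor, at 4.21 ± 0.39 log2, and STE2 at 2.64 ± 0.40. With quantile-normalized arrays 13 of the 26 pheromone genes and 4 of the 7 MATa genes remained higher, all of them among the 20 and 5 called before, the median deviations fell to 1.31 and 1.33 log2, and the deviations of FIG1 (adjusted p = 0.678) and AGA1 (0.0983) did not pass.

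**Figure D3:**
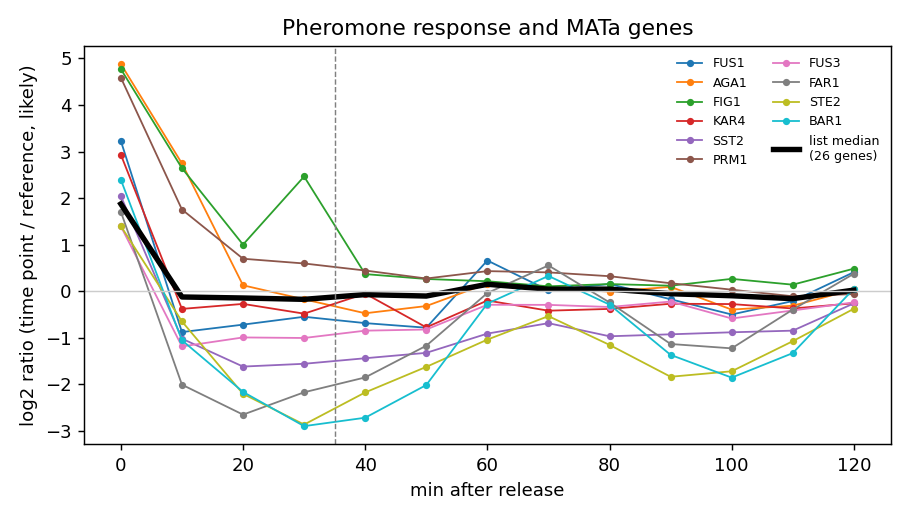
Log2 ratio to the asynchronous reference (y axis) against min after release (x axis) for 10 pheromone-responsive and MATa-specific genes (thin lines) and the median of the pheromone response list (thick line), with a dashed line between the array sets. The list median is 1.88 at 0 min, -0.12 at 10 min and between -0.17 and 0.15 afterwards.

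Other groups also departed from the curve at 0 min. Of 40 ribosome biogenesis genes 12 were higher (25 adjusted over the list alone), with a median deviation of 0.57 log2, although with quantile-normalized arrays only 1 was higher (median 0.28 log2) and without the array set 3 (median 0.39 log2), and the period gave 7 at 55 min and 20 at 65 min. Of 33 replication and repair genes 7 were lower (16 adjusted over the list alone), with a median of -0.89 log2, and 1 was lower with either of those changes (medians -0.61 and -0.49 log2). The median log2 ratio of this list was -0.57 at 0 min, but 0.95 and 1.07 at 10 and 20 min. Its median difference from the mean of 60 and 120 min was only -0.24 log2. By more than those 2 arrays differed, 16 genes were lower and 5 higher. Part of the deviation may therefore describe the curve's high value at 0 min. Leaving out 1 array gave between 3 (without 10 min) and 11 (without 30 min) lower genes, with 4 without 20, 70, 80, 90 or 110 min, and the period gave 2 at 55 min and 20 at 65 min. The G1 cyclin CLN1 lay 5.24-fold below its curve (-2.39 ± 0.32 log2) and CLB6 6.04-fold (-2.59 ± 0.64), though neither passed with quantile-normalized arrays (adjusted p = 0.0726 and 0.079). CLB6 passed narrowly (adjusted p = 0.0368) and also missed the threshold without the array set (0.126), at 55 min (0.147), with robust shrinkage (0.054), with values at the limit kept (0.0615) and without any 1 of the arrays at 20, 50, 70, 80, 90 or 110 min (0.0517 to 0.0879). HHO1, the linker histone, lay at -2.32 ± 0.37. The other lowest genes were YMR326C (-4.36 ± 0.32), the mitochondrial dicarboxylate carrier DIC1 (-3.58 ± 0.61), TOS6 (-3.31 ± 0.43), the carbonic anhydrase NCE103 (-2.92 ± 0.49) and THI12 (-2.71 ± 0.37), which has near-identical copies and whose call was lost when values at the limit were kept (adjusted p = 0.266). Of the SIC1 cluster 6 of 23 genes were higher (6 adjusted over the list alone, beside 1 lower), among them the cell separation genes SCW11 (5.22 ± 0.63 log2), DSE2 (5.13 ± 1.10) and AMN1 (4.48 ± 0.61). Of this cluster 3 genes were higher without the 80 or the 90 min array and 2 with quantile-normalized arrays. In DSE2 the ratio itself was -1.34 log2 at 0 min, so the deviation describes the curve's low value there. Without the array set none of these 3 passed (adjusted p = 0.354, 0.721 and 0.649), and the median deviation of the cluster turned from 0.93 to -0.32 log2. DSE2 did not pass with quantile-normalized arrays either (adjusted p = 0.0543). BSC1 was higher by 3.62 ± 0.45 log2, with a ratio of -0.29 log2 at 0 min and -2.49 or lower on the other arrays, and did not pass with quantile-normalized arrays (adjusted p = 0.231). The calls of FAR1 and NCE103 were also lost without the array set (adjusted p = 0.356 and 0.705). NCE103 had a ratio of -0.16 log2 at 0 min and of 3.01, 2.24 and 1.82 at 10, 20 and 30 min, so its deviation describes the curve's high value at 0 min. The remaining lists held few calls. In budding and cell wall 2 were higher and 4 lower (3 and 7 adjusted over the list alone), in spindle 4 were lower (7), in stress response 2 (2), in ECB genes 1 (2), in histones 1 (1), and in meiosis and oxidative phosphorylation 1 each (1 and 1). The G2/M cluster and the methionine, phosphate, ribosomal protein, proteasome, glycolysis and MATalpha lists held none by limma, with 7, 5, 7, 0, 0, 4 and 0 genes at an unadjusted p under 0.05. Adjusted over the list alone, only the phosphate list among these had calls, with 1 higher and 3 lower. Even so, the median deviation lay below the range of 95% of random lists of the same size for histones (-1.01 log2), the G2/M cluster (-0.59), phosphate (-0.51), spindle (-0.40), budding and cell wall (-0.33), ECB genes (-0.31), oxidative phosphorylation (-0.25) and glycolysis (-0.18), and within that range for stress response, meiosis, ribosomal proteins, proteasome and MATalpha. Random lists do not hold genes that move together as these lists do.

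The 0 min sample was also set against the nominal starts of the later cycles, at 60 and 120 min. These arrays need not match 0 min in the cycle, since the best period was 64 min. The median log2 ratio of the G2/M cluster was 0.71 at 60 min and 0.59 at 120 min, against -0.58 at 0 min. All 26 pheromone response genes were higher at 0 min by more than 60 and 120 min differed from each other, with a median difference of 1.64 log2, and so were all 7 MATa-specific genes (median 2.50 log2). Ribosome biogenesis genes were higher by this rule in 28 of 40 cases and lower in 0. In the G2/M cluster 19 of 23 genes were lower and 1 was higher, with a median of -1.27 log2. Methionine genes were higher in 14 of 22 cases and lower in 1, while their median deviation from the fitted curve at 0 min had the opposite sign, -0.34 log2 (95% of random lists from -0.16 to 0.16). The SIC1 cluster also went the other way than against its curve: 13 of 23 genes were lower than at 60 and 120 min and 3 higher, with a median of -0.45 log2. Over all 6111 genes with the 3 values, 1727 were higher and 1566 lower by the same rule, which is not a test. The 0 min array belongs to set A and the later 2 to set B, so these differences alone do not separate the arrest from the array set. Nor do they separate the arrest from a different place in the cycle at 60 and 120 min. For the pheromone response list the other set A arrays had median log2 ratios of -0.12, -0.15 and -0.17 at 10, 20 and 30 min, against 1.88 at 0 min, so the set as a whole does not carry its difference.

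The third question was how far the second cycle repeats the first. Across genes, arrays 60 min apart correlated with a median r of 0.594 and arrays 30 min apart with 0.350, or 0.384 and 0.242 with values at the limit kept. The 0 min array was the exception, with 0.235 at 60 min and 0.240 at 30 min, while the 50 min array reached 0.683 and 0.376. Genes are not independent replicates, and much of this correlation is an offset that each gene keeps over the arrays. Every time point was labelled with Cy5, so the offset may be a level against the shared reference or a bias of dye or spot. After each gene was centred, the medians were 0.029 and -0.384 over all genes, and 0.356 and -0.612 over the 161 phase list genes. In these genes r with the array 60 min later was -0.004 (-0.00435) for 10 min and 0.127 for 20 min, 0.299 for 0 min and 0.413 for 30 min, and 0.569 and 0.654 for 40 and 50 min. The first 4 of these pairs join set A to set B and the last 2 lie within set B, and the set was not taken out here, so low values in the first 4 can come from the set as well as from the cycle. The swing of the mean profile was smaller in the second cycle for 6 of 7 phase lists. The ratio of the second range to the first was 0.492 for replication and repair, 0.914 for budding and cell wall, 0.668 for histones, 0.418 for spindle, 0.512 for G2/M and 0.569 for ECB genes. The SIC1 cluster went the other way, with 1.42, but not for 10 to 60 min against 70 to 120 min, where all 7 lists had a smaller second range. In both choices of window the first range joins set A to set B and the second lies within set B. The set was not taken out of the ranges either, so an offset between the sets can change the ratios. The ratios were not tested, and a limma test for different curves before and from 60 min called 0 of 6183 genes, with 604 at an unadjusted p under 0.05. That model lets the rhythm change at 60 min but not the level, so genes whose level also shifts there can be missed. Differences smaller than the planted 2 log2 were not simulated and can be missed too. The 0 calls therefore do not show that all genes repeat their curve.

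**Figure D4:**
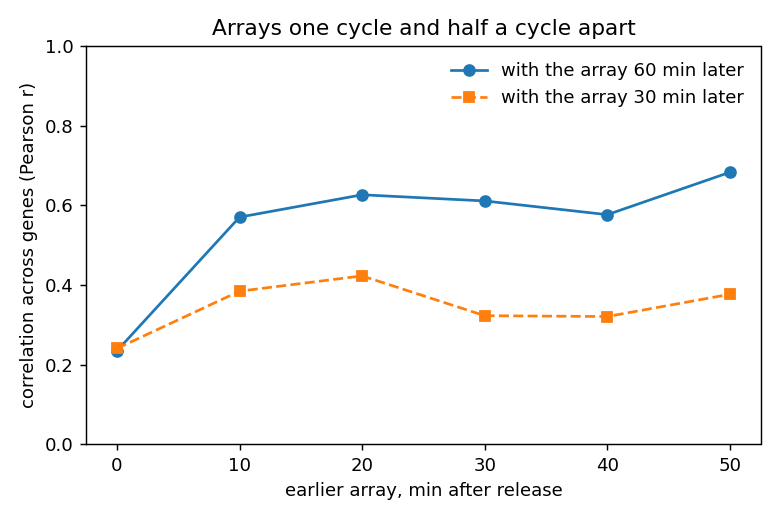
Pearson r across genes (y axis) between the array at each time (x axis, min after release) and the array 60 min later (circles) or 30 min later (squares). From 10 min on the 60 min partner correlates more, with 0.570 to 0.683 against 0.321 to 0.423.

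The period that left the smallest residual over the phase list genes was 64 min, and it was 64 or 65 min when any 1 array was left out. Without the array set in the fit it was 66 min.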

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

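The ratios of ranges with quantile normalization and without the 0 min array were planned, and the bounds they are held to and the other tests in this part were chosen after the results were seen. No group holds more than 1 array, so no array could be compared with others of its group. Among the control rows, which no comparison used, some carried strong ratios on some arrays. What these rows hold is known only from their names. The row named blank in angle brackets had a median log10 ratio of 1.9953 over 0 to 30 min and 1.98 at 60 min. The row named empty had a median of 1.9864 and a value of 1.47 at 60 min. On the other 8 arrays the first of these rows lay between -1.85 and 0.40. A further row named blank, without brackets, stayed between -0.06 and 0.03 (-0.0584 to 0.0321) on all 13 arrays, and the Human Control row between 0.06 and 0.49. Other control rows were high on some of the set A arrays, Lambda Control with 1.83, 2 and 2 at 0, 10 and 30 min (0.0138 at 20 min) and Phi174 Control with 2 at 10 min and 1.0043 at 20 min.

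Such a ratio on spots without a target may come from 1 channel being close to zero there, since any signal in the other then gives an extreme ratio. If so, the same arrays should hold more gene values at the deposited limit. The 5 arrays with the high row had a median of 27 such values (23 to 107), and the other 8 a median of 4.5 (0 to 14). An exact two-sided permutation test of the difference of means gave p = 0.000777, the smallest its 1287 splits can give. The row named blank near 0 on the same arrays goes against a dim channel on all empty spots, unless its spots hold something, so this stays open. No biological explanation was tested, and the array set stays open too, since 4 of the 5 arrays form set A.

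The number of genes that deviate at 0 min was set against noise of that array. The same indicator called 135 genes at 10 min and 129 at 60 min, and 1 to 13 on each other array. For the pheromone response list, the bound set for noise was the range of random lists of its size (up to 0.15 log2 on either side). Random lists do not hold genes that move together, and this list passed that bound on other arrays too, with -0.70 log2 at 10 min and 0.79 at 80 min. That bound alone therefore cannot exclude noise. The median deviation at 0 min was 2.11 log2, against at most 0.79 in size on any other array. Which sign it has rests on the assumed direction, and its size does not. For genes in no list the 256 calls at 0 min compare with 122 such calls at 10 min and 122 at 60 min, so noise, curve misfit and the arrest cannot be told apart there. The response to pheromone, which the design names, remains the candidate explanation for the list and was not tested otherwise.

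The smaller swing of the second cycle may come from the wider spread of the set A arrays, which enter only the first cycle. With equal spread on all arrays (quantile normalization) the median ratio of ranges went from 0.569 to 0.834, with 5 of 7 lists smaller, and it stayed within 1 SD over the lists (0.350) of 1, so this explanation stays open. Without the 0 min array the ratio was 0.631 when its partner was also left out (6 of 7 lists smaller), below 1 by more than that SD. It was 0.667 for 10 to 60 min against 70 to 120 min (7 of 7 smaller, the SIC1 cluster included), within that SD. By that bound the 0 min array as the cause stays open too. Most or all lists kept a smaller second range without it, though, which argues against that array as the only cause. An offset of the genes between the sets can also change the first range, which alone joins both sets. Quantile normalization does not take out such an offset, and this was not tested. Loss of synchrony, the biological alternative, stays open and was not tested. Against chance as the source of the 338 periodic genes, 1 of 100 orders of the arrays within their sets, the real one included, called as many, and the highest other order called 1.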

How the results depend on the processing

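Keeping the values at the limit, centring the genes before correlating, the test for different curves in both cycles and the indicator on each other array were chosen after seeing the data. No paired analysis was possible because each time point has 1 array. The cause of the changes below was not tested. The 338 periodic genes became 548 with quantile normalization (335 shared), 0 at 50 min, 6 at 55 min and 210 at 70 min, 73 with a second harmonic, 107 without shrinkage and 62 at an adjusted p under 0.01. Leaving out 1 array gave 143 (without 70 min) to 382 (without 10 min), with 196 without 30 min, 191 without 40 min, 197 without 50 min, 151 without 80 min and 209 without 90 min. Other settings gave 252 to 414. Without the array set 271 of 384 calls were shared with the 338, and within set B alone 212 of 298. Between 4 and 7 phase lists passed, against 6, over the scalings, filters, array set terms, 55 min, 65 min and best periods, median profile and left-out arrays run for them. Of 1468 values of named periodic genes under an alternative, 37 gained a call, 278 lost it, and a further 2 lost it with a peak that moved far. These were CDC20 (1.08 log2) and SCW10 (0.97 log2) at 50 min, with fitted peaks at 11.1 and 36.2 min.

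The 322 deviations at 0 min became 89 with quantile normalization (47 higher, 42 lower), 556 at 65 min (304 higher, 252 lower) and 501 at the best period (224 lower). Without the array set 82 were lower. Leaving out 1 array gave 214 (without 90 min) to 367 in all, and 75 (without 80 min; 77 without 90 min) to 165 lower. Over the named genes, 23 of 483 values at 0 min under an alternative lost their call and none changed sign. The pheromone list's difference between 0 min and later arrays was 1.22 log2 (1.215) with quantile normalization and 1.83 against 60 min alone. With values at the limit kept, the median correlations fell to 0.384 (60 min apart) and 0.242 (30 min apart), and with centred genes to 0.029 and -0.384. The best period was 66 min without the array set. The ratio of ranges lay between 0.569 and 0.834 and the sign of the direction check held under every scaling. Signal over background is not given, so the noise of weak spots could not be separated.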

Other observations

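The tests in this part were chosen after the results were seen. Genes that attach sugars to secreted proteins formed a group the lists hardly covered. Protein O-mannosyltransferases start the mannosylation of cell wall proteins. PMT1, PMT2, PMT4 and PMT5 were periodic by limma, with 0.76 ± 0.14, 0.65 ± 0.14, 0.81 ± 0.13 and 1.04 ± 0.21 log2 (SE) and peaks at 27.8, 28.8, 30.4 and 26.8 min. PMT3, PMT6 and PMT7 did not pass (adjusted p = 0.0658, 0.456 and 0.0733). Over all 25 measured genes named PMT, ALG or OST, 6 were periodic where 1.37 would be by the overall share, ALG2 and ALG14 being the other 2. The group was picked because members were seen among the calls, so these counts are no test of it. The mean profile of the 19 members that were not called spanned 0.20 log2 with a peak at 28.4 min (permutation p = 0.00918). Of these, ALG5, PMT3, ALG7 and PMT7 lay just past the threshold (adjusted p = 0.0518 to 0.0733), and 13 had an unadjusted p of 0.114 or more, with peaks from 1.9 to 59.2 min. A few members may therefore carry that profile.

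The 7 YRF1 genes, helicase genes of the Y' elements at chromosome ends, were all periodic, with peaks between 14.5 and 15.8 min and sizes between 1.40 and 1.55 log2. Of the 160 measured genes that are among the outermost 5 of a chromosome end, 23 were periodic, where 8.75 would be by the overall share, and 22 of them peaked between 13 and 17 min. Shared sequence is a candidate explanation for their agreement, since Y' copies are near-identical. The residuals around the curve correlated with a median r of 0.924 between YRF1 genes, 0.789 between the other 15 of the 22 end genes, and 0.134 between 26 other called genes of the same peak window. The YRF1 copies may therefore not be separate measurements. Residuals also hold curve misfit, which genes with a common course share, so this correlation cannot tell shared signal from shared control. Without the 22 end genes the periodic count is 316. Whether 1 copy or several oscillate cannot be read from these arrays.

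Neighbouring periodic genes peaked close together. In 34 pairs of measured neighbours that were both periodic, away from chromosome ends, the median difference of the peaks was 4.41 min, against 13.1 min after shuffling the peaks. Without the 4 pairs of histone genes it was 4.64 min in 30 pairs (one-sided permutation p = 5e-05, the smallest 20000 shuffles can give). The 11 divergent pairs among these, which share an upstream region, had 4.80 min (permutation p = 0.00975), and the 19 tandem or convergent pairs 4.48 min (permutation p = 0.00075). Examples are SMC3 with JEM1 (0.49 min apart) and TOF1 with SEC2 (0.63 min), while MCM3 and SPF1 peaked 24.7 min apart. Shared control of neighbours may contribute. Both kinds of pairs were closer than shuffled peaks give and were not tested against each other. Overlapping transcripts or spots that pick up both remain open, as these arrays are not known to separate strands.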
